A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

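RNA sequencing libraries were made from total RNA of budding yeast (Saccharomyces cerevisiae, strain BY4741, a laboratory derivative of the reference strain S288C). Per the labels' protocols, cells were taken in exponential growth in YPD, a rich medium with glucose, or in sucrose. Total RNA was taken by acid phenol extraction and checked on a Bioanalyzer, and libraries were made with a KAPA kit. Whether ribosomal RNA was removed or polyadenylated RNA selected is not given in the sources used here. There were 12 libraries in 4 groups of 3: WT in glucose, the mutant labelled Rpd3-2SA in glucose, WT in sucrose and Rpd3-2SA in sucrose. Groups and replicate numbers were taken from the sample titles, and the design text calls the replicates biological. The labels do not spell out the 2SA change or how that strain was made.

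The authors deposited a single table of raw read counts per gene, whole numbers with no normalization, with 7127 features and 12 columns. Reads were aligned with Bowtie 0.12.2 to the sacCer3 genome, per the submitters' processing notes. The program that counted reads, its treatment of reads with several matches and its strand setting are not given in the sources used here. Reads of overlapping or antisense genes can therefore not be told apart, and values of genes with near-identical copies are uncertain. Coordinates are those of the table, in sacCer3. The R64 reference annotation has the same start for 99.9% of the 6047 features with a matching locus tag. Library totals ran from 20775911 to 25360037 counts. At that depth a sum of 0 counts over all libraries allows at most 0.0109 CPM (counts scaled to library size, with a limit of 3 counts and counting error only). No pair of replicates was close enough to be 1 library deposited more than once, with chi-square per degree of freedom of 87.4 or more.

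Counts were tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16, with 1 mean per group, all 12 libraries in 1 fit and 8 residual degrees of freedom. Libraries were scaled by the trimmed mean of M values (TMM, factors 0.922 to 1.11). The default filter (minimum count 10) kept 6085 features and left 1042 untested. The common dispersion was 0.0719. A gene was called where the Benjamini-Hochberg adjusted p was under 0.05 and the fold change over 1.5, the thresholds of the series' design text. Adjusted p of genes and standard errors of log2 fold changes come from this fit, or from the same edgeR test in the fit with the block within carbon source where values are given with that block. CPM values are TMM-scaled group means ± SD with n = 3, unless given as a share or range over libraries. The 5 contrasts were 2SA against WT in glucose and in sucrose, sucrose against glucose in WT and in 2SA, and the interaction, which is the difference of the sucrose responses.

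Gene lists for 35 pathways, complexes and gene families were fixed before the data were examined, as were the tests, the thresholds and most alternatives. The lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes. Lists needed 4 tested members, which 33 had, and p-values were adjusted over lists within a contrast. The list of mitochondrially encoded genes had no tested member and that of alpha-specific genes too few. Each list was also tested with an estimated correlation and with fry. No list passed in any contrast with an estimated correlation. The median, the mean and the test had the same sign in every list said to pass. Members of a list were counted over all genes tested and adjusted over the list alone.

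Genes are named by a rule with 3 parts. In each contrast it takes, among called genes with non-overlapping replicates and a mean of at least 5 CPM in the higher group, the 6 with the largest increase and the 6 with the largest decrease. It adds up to 4 called members of each list, and always RPD3, SIN3, UME6, SUC2, HXT1, HXT7, HXK2, INO1, IME2, HIS3, LEU2, URA3 and MET17. Near copies were found with BLAST+ 2.17.0 as matches of at least 80% identity over at least 100 bp.

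The replicate numbers were taken to pair libraries where the deviations of every same-numbered pair correlated with r over 0.1. Deviations from the group means, over genes, correlated between WT and 2SA libraries of the same number with r = 0.654, 0.610 and 0.545 in glucose and 0.603, 0.847 and 0.799 in sucrose. The numbers thus pair WT with 2SA libraries within each carbon source, as a feature of the data that the labels do not explain. The planned block has the replicate number as an additive term. These correlations and the calls of the planned block were computed together, so the check did not precede the calls. A block for each pair of libraries, the number within its carbon source, was added after both had been seen, with 4 residual degrees of freedom and a common dispersion of 0.0134. Its values are printed beside the comparisons of 2SA with WT.

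Alternatives, given in the closing section, were size factors of DESeq2 1.42.0 (RLE), scaling by total count, no filter, a filter at a mean of 10 CPM, the DESeq2 Wald test, limma-voom, other fold thresholds, glmTreat, fits of the compared groups alone and leaving out each library. Leaving out all libraries of 1 number was added after the data were seen. The pipeline was tested on simulated counts. With independent libraries, 37 of 100 genes changed by a fold of 2 and 89 of 100 changed by a fold of 4 were recovered for 2SA against WT in glucose (8 false calls among 6063 genes). For the interaction 7 and 67 of 100 were recovered (6064 genes). Where simulated libraries shared their deviations by number, the block within carbon source recovered 92 of 100 genes changed by a fold of 2 in glucose, against 51 without it (6061 genes). It made 7 false calls there, against 0 without it. With independent libraries it recovered 29 of 100 in glucose, against 37 without it. The shared deviations were drawn from the block fit itself, so this shows the gain where pairing holds and not that it holds.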

Results

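The data set holds 12 RNA sequencing libraries from WT yeast and from a mutant of RPD3, the gene of a histone deacetylase that represses many genes as part of Sin3 complexes. By its title the series asks how phosphorylation of Rpd3 affects gene expression in glucose and in sucrose. Each of the 4 groups (WT and 2SA, in glucose and in sucrose) had 3 biological replicates. Library totals lay between 20775911 and 25360037 counts. RPD3 itself (YNL330C, chromosome XIV, 18001 to 19302) had 88.2 to 150 CPM by library total in the 12 libraries. Its log2 fold change in 2SA was 0.02 ± 0.18 in glucose and −0.02 ± 0.18 in sucrose (edgeR adjusted p = 1.0 and 0.998). Its count does not show whether a library carries the mutation. Without a block, SIN3, UME6, HXT7, HXK2, INO1 and IME2 were not called in 2SA against WT in either carbon source. By library total, IME2 had 18.3 ± 4.59 CPM in WT and 19.4 ± 4.24 in 2SA in glucose, and 18.0 ± 6.88 and 19.6 ± 5.74 in sucrose. INO1 had 9.66 ± 2.67 and 12.3 ± 4.69 in glucose, and 22.6 ± 5.37 and 52.1 ± 37.7 in sucrose. The list of Ume6- and Rpd3-repressed genes passed in neither comparison. Its members CAR2 and CAR1 were called higher in 2SA in glucose with the block within carbon source. Their log2 fold changes were 0.85 and 0.62 (edgeR adjusted p = 0.0314 and 0.0441), and both calls were lost without the libraries numbered 2. For the mean effect of both carbon sources with that block, 1 member of the list was higher and 3 were lower. Of the marker genes, MET17 had no count in any library and LEU2 had 1 count in all libraries together. URA3 lay between 252 and 491 CPM and HIS3, which overlaps another annotated feature, between 32.2 and 69.4 CPM, over libraries of both genotypes. BY4741, the strain named in the labels, is known to lack URA3 and part of HIS3. The counts of URA3 go against that label in all 12 libraries, and the cause was not tested.

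In glucose, 3 genes were called lower and 2 features higher in 2SA. SNZ3 (YFL059W, a vitamin B6 synthesis gene on chromosome VI, 11363 to 12259) fell from 28.5 ± 12.7 to 2.43 ± 0.714 CPM, a log2 fold change of −3.55 ± 0.48 (adjusted p = 0.0210, n = 3 per group). ADH7 (YCR105W, an alcohol dehydrogenase gene on chromosome III, 309070 to 310155) fell from 12 ± 1.3 to 3.14 ± 0.829 CPM (log2 −1.94 ± 0.22, adjusted p = 0.00691). YIL171W, a feature beside the hexose transporter pseudogene HXT12, fell by 1.23 ± 0.17 on the log2 scale (adjusted p = 0.0244). The feature YDR365W-B, an open reading frame of a Ty retrotransposon on chromosome IV (1206997 to 1212265), rose from 3.55 ± 0.429 to 24.8 ± 2.78 CPM (log2 2.80 ± 0.22, adjusted p = 3.76e-04). For each of these genes the 3 replicates of 2SA lay apart from the 3 of WT. SNZ3, YIL171W and YDR365W-B have near-identical copies, so their values are uncertain. ETS1-1, a spacer of the ribosomal RNA genes with a near-identical copy in ETS1-2, was the remaining call, named here after its values were seen (2.21 ± 1.09 CPM in 2SA and 0.0303 ± 0.0524 in WT, adjusted p = 0.0112).

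Across 6085 genes, 2 were called higher and 3 lower in 2SA in glucose, and 171 had an unadjusted p under 0.05 where chance gives 304 (639 with the block within carbon source). The fit without a block counts deviations that WT and 2SA libraries of a number share as spread between replicates. Its common dispersion was 0.0719, against 0.0134 with the block within carbon source. Few calls without a block therefore do not show that 2SA had little effect. DESeq2 called 5 higher and 26 lower. With the planned replicate block 2 were higher and 7 lower. With the block within carbon source 7 were higher and 22 lower, and both sets held all 5 genes called without a block. In that blocked fit the secreted acid phosphatase gene PHO11 fell from 33.1 ± 8.34 to 9.23 ± 2.99 CPM (log2 −1.85 ± 0.14, adjusted p = 4.5e-04). Also lower were the phosphate transporter gene PHO89 (log2 −1.38 ± 0.15), the glycerophosphoinositol permease gene GIT1 (−1.39 ± 0.19) and PHO12 (−0.90 ± 0.13, a near copy of PHO11). The allantoin permease gene DAL4 (log2 −2.68 ± 0.38), the glutathione exchanger gene GEX2 (−2.59 ± 0.23), IMD2 of guanine nucleotide synthesis (−1.21 ± 0.18), COS7 (−1.32 ± 0.11) and COS5 (−1.11 ± 0.17) were lower as well. GEX2, IMD2 and the COS genes have near copies. Higher in 2SA were SNO1 of vitamin B6 synthesis (log2 0.92 ± 0.14) and the arginine catabolism genes CAR2 (0.85 ± 0.13) and CAR1 (0.62 ± 0.10). Both CAR genes are on the list of Ume6- and Rpd3-repressed genes. The Ty features YNL284C-B (1.57 ± 0.25) and YDR261C-D (1.55 ± 0.26) were higher too and have near-identical copies. CAR2 overlaps another annotated feature. With all libraries numbered 2 left out of this fit, which leaves fewer libraries, PHO11, PHO89, GEX2 and COS7 kept their calls. The other genes named with the block lost theirs and kept their direction (adjusted p 0.0564 to 0.241). Their log2 fold changes were larger in size there, except for DAL4 (−2.66).

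8 of the 33 lists tested ranked lower than other genes in 2SA in glucose, and 10 passed with the block within carbon source. The list of hexose transporters and glucose sensors had a median log2 fold change of −0.24 over 17 genes (camera adjusted p = 5.55e-07, adjusted p = 0.354 with an estimated correlation). None of its members was called over all genes, and 4 were lower when adjusted over the list alone. Genes of sucrose and alpha-glucoside use had a median of −0.21 over 12 genes, with 0 called and 3 lower adjusted over the list alone (adjusted p = 1.97e-04, adjusted p = 0.545 with an estimated correlation). In the phosphate regulon the median was −0.23 over 25 genes, with 0 called and 1 lower adjusted over the list alone, and with the block 4 called and 5 lower adjusted over the list alone (adjusted p = 1.67e-04, with the block 9.07e-07). The PAU and COS families, which lie near chromosome ends, had a median of −0.16 over 29 genes with 1 lower adjusted over the list alone, and with the block 2 called and 8 lower adjusted over the list alone. Middle and late sporulation genes (median −0.37, 26 genes), a-specific mating genes (−0.39, 7 genes), haploid-specific and pheromone genes (−0.21, 20 genes) and cell wall genes (−0.09, 29 genes) passed as well. In the fit without a block none of their members was called, and none when adjusted over the list alone. For the phosphate list and the lists named after it, adjusted p = 0.354 with an estimated correlation. With the block too, no list passed with an estimated correlation (lowest camera adjusted p = 0.147). Peroxisome genes (higher, median 0.16, adjusted p = 0.0370) and ribosomal protein genes (lower, median −0.05, adjusted p = 0.0155) passed with the block alone, with adjusted p = 0.797 and 0.887 with an estimated correlation in that fit.

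Without a block, some calls in glucose were lost when a single library was left out, which leaves fewer libraries for the test. SNZ3 lost its call when 1 of the WT libraries numbered 2 or 3 or any of the 3 mutant libraries was left out (adjusted p = 0.0968, 0.0967, 0.220, 0.229 and 0.0871), and ADH7 without WT library 3 or 2SA library 1 (adjusted p = 0.0501 and 0.0570). YDR365W-B kept its call without any single library, while YIL171W lost it without any 1 of the 6 glucose libraries (adjusted p 0.0504 to 0.245) or without 2SA sucrose library 3 (adjusted p = 0.0533). Without WT library 1, 2 or 3 the lower calls in glucose numbered 4, 1 and 0, and without 2SA library 1, 2 or 3 they numbered 0, 1 and 1. The higher calls numbered 1 without WT library 2 or 3. In the fit with the block within carbon source, SNZ3, ADH7 and YDR365W-B kept their calls without all libraries numbered 2. Their edgeR adjusted p was 0.0129, 0.0303 and 0.0129 there, while YIL171W lost its call (adjusted p = 0.158).

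**Figure D1:**
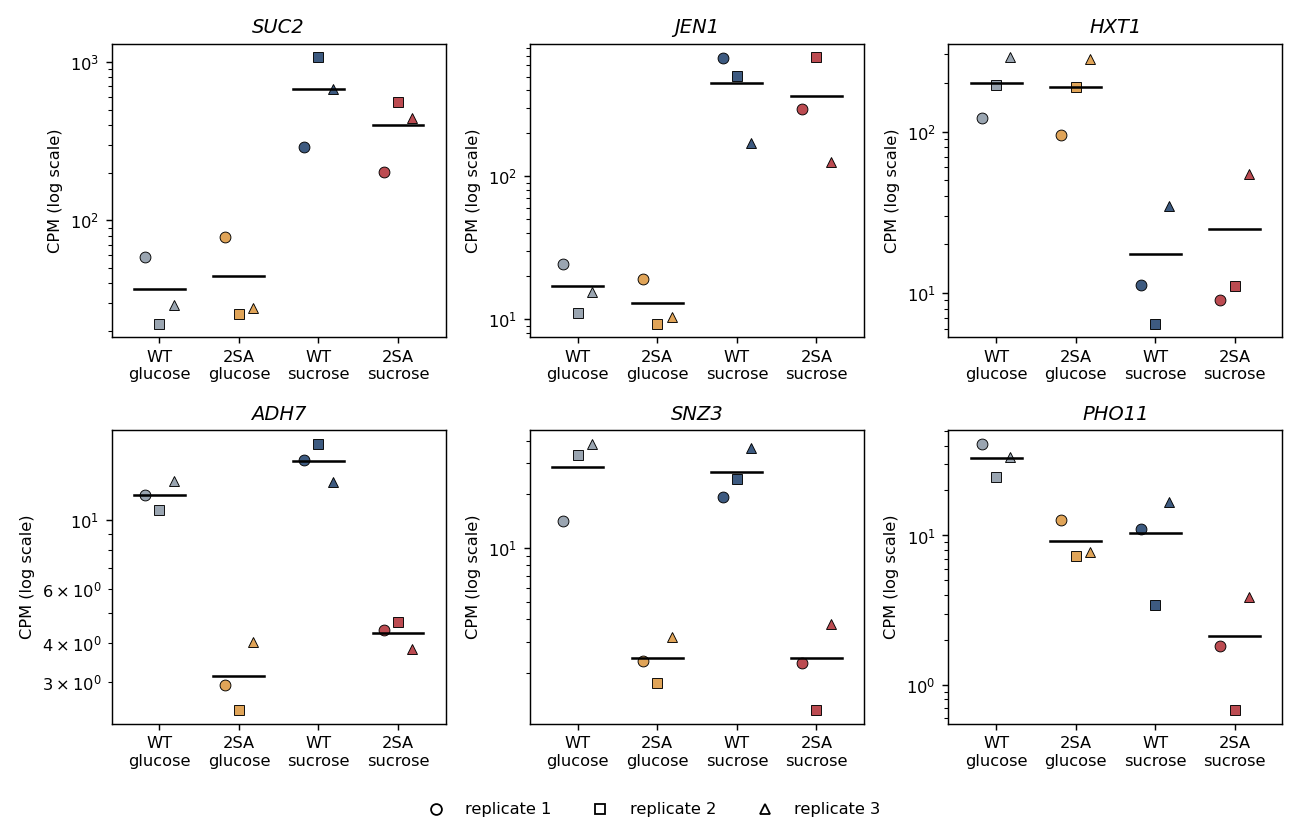
TMM-scaled CPM on a log axis of SUC2, JEN1, HXT1, ADH7, SNZ3 and PHO11 in the 12 libraries, with 1 symbol per replicate number and a line at the mean of each group of 3. ADH7 and SNZ3 lie lower in every 2SA library than in any WT library, while SUC2 and JEN1 lie higher and HXT1 lower in every sucrose library than in any glucose library.

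In sucrose, ADH7 and SNZ3 were again lower and YDR365W-B again higher in 2SA. ADH7 fell from 15.5 ± 2.17 to 4.32 ± 0.429 CPM (log2 −1.84 ± 0.21, adjusted p = 0.00986, n = 3 per group) and SNZ3 from 26.7 ± 8.77 to 2.42 ± 1.26 CPM (log2 −3.48 ± 0.48, adjusted p = 0.0331). YDR365W-B rose from 2.60 ± 0.573 to 13.8 ± 2.60 CPM (log2 2.40 ± 0.22, adjusted p = 0.00177). DDI3, which encodes a cyanamide hydratase and has the near-identical copy DDI2, fell from 1.91 ± 0.525 to 0.271 ± 0.0759 CPM (adjusted p = 0.0431) and is named after its values were seen. Without a block these were the only calls, 1 higher and 3 lower, and 242 genes had an unadjusted p under 0.05 where chance gives 304 (1292 with the block within carbon source). As in glucose, the fit without a block counts shared deviations as spread, so its few calls do not show a small effect. DESeq2 called 10 higher and 36 lower.

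The planned replicate block gave 1 higher and 9 lower, and the block within carbon source 14 higher and 98 lower. In the latter fit 5 of 17 hexose transporter and glucose sensor genes and 4 of 12 genes of sucrose and alpha-glucoside use were lower in 2SA. Of these lists 6 and 11 genes lie within 30 kb of a chromosome end. SUC2 (YIL162W, chromosome IX, 37385 to 38983), the gene of the invertase that splits sucrose, fell from 677 ± 388 to 401 ± 182 CPM (log2 −0.69 ± 0.11, adjusted p = 0.0181). Without the block its log2 fold change was −0.76 ± 0.59 (adjusted p = 0.998), as the replicates of the groups overlapped while 2SA was lower in 3 of 3 pairs. The maltose transporter genes MPH3 (log2 −1.52 ± 0.33) and MPH2 (−1.40 ± 0.30), the isomaltase gene IMA2 (−1.19 ± 0.25) and the transporter genes HXT15 (−2.07 ± 0.37), HXT11 (−0.95 ± 0.17), HXT13 (−0.89 ± 0.18) and GAL2 (−0.86 ± 0.16) also fell, all but GAL2 with near copies. Of the phosphate regulon, PHO11 fell from 10.4 ± 6.69 to 2.13 ± 1.63 CPM (log2 −2.33 ± 0.16, adjusted p = 2.79e-04), with PHM6 (−1.59 ± 0.27), GIT1 (−1.58 ± 0.19) and SPL2 (−1.29 ± 0.16). Glycolytic isozyme genes TDH1 (log2 −1.23 ± 0.10), PYK2 (−0.93 ± 0.16), HXK1 (−0.71 ± 0.13) and ENO1 (−0.63 ± 0.14) were lower. So were the stress genes TMA10 (−1.11 ± 0.17), HSP26 (−0.81 ± 0.17), PAI3 (−0.76 ± 0.15) and MSN4 (−0.67 ± 0.13), and the glycogen phosphorylase gene GPH1 (−1.02 ± 0.17). MIG1 (−0.63 ± 0.07) and CAT8 (−0.61 ± 0.09), which encode regulators of glucose-repressed genes, fell as well. The vitamin B6 genes moved in both directions, with SNZ1 (log2 1.15 ± 0.13) and SNO1 (1.11 ± 0.13) higher and SNO2 (−1.31 ± 0.18) and SNZ2 (−1.19 ± 0.22) lower. THI72, a relative of the thiamine transporter gene THI7, (log2 1.0 ± 0.16) and the urea permease gene DUR3 (0.72 ± 0.15) were higher. In the glycolytic, stress and regulator genes named here the replicates of WT and 2SA overlapped as well, with 2SA lower in 3 of 3 pairs. HXK1 and GPH1 overlap other annotated features, and PHO11, TDH1, ENO1, SNZ2, SNO2 and THI72 have near copies. With all libraries numbered 2 left out of this fit, which leaves fewer libraries, PHO11, PHM6, SPL2, TDH1 and SNO1 kept their calls. The other genes named with the block lost theirs and kept their direction (adjusted p 0.0542 to 0.311), with adjusted p = 0.139 for TMA10 and PAI3, 0.291 for HSP26 and 0.293 for MSN4.

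15 lists passed in sucrose, 13 lower and 2 higher in 2SA, and 20 with the block within carbon source. Among those that joined with the block were the stationary phase list (median −0.29, adjusted p = 0.0312) and ergosterol genes (0.11, adjusted p = 0.0470), with adjusted p = 0.366 and 0.674 with an estimated correlation. Hexose transporters and glucose sensors had a median of −0.80 over 17 genes (camera adjusted p = 3.58e-09, adjusted p = 0.231 with an estimated correlation). 4 members were lower adjusted over the list alone, and with the block 5 were called and 9 lower adjusted over the list alone. For sucrose and alpha-glucoside use the median was −0.67 with 3 of 12 lower adjusted over the list alone, and with the block 4 called and 6 adjusted over the list alone (adjusted p = 1.75e-05, adjusted p = 0.512 with an estimated correlation). In the phosphate regulon the median was −0.38 with 4 of 25 lower adjusted over the list alone, and with the block 8 called and 9 adjusted over the list alone (adjusted p = 7.9e-09, adjusted p = 0.231 with an estimated correlation). The a-specific genes had a median of −0.55, with 3 of 7 lower adjusted over the list alone, among them the pheromone protease gene BAR1 with the block (log2 −0.88 ± 0.19; adjusted p = 0.231 with an estimated correlation for the list). The PAU and COS families had a median of −0.30 with 4 of 29 lower adjusted over the list alone (adjusted p = 1.12e-04, adjusted p = 0.240 with an estimated correlation). Middle and late sporulation genes had a median of −0.52 with none of 26 adjusted over the list alone and 7 with the block (adjusted p = 2.99e-05, adjusted p = 0.505 with an estimated correlation).

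The general stress response list was lower in 2SA in sucrose with a median of −0.47 over 38 genes, 6 of them called and 9 adjusted over the list alone with the block and none without it (adjusted p = 2.48e-05, adjusted p = 0.923 with an estimated correlation). Glycolysis had a median of −0.27 with 4 of 21 called with the block (adjusted p = 2.25e-04, adjusted p = 0.744 with an estimated correlation). The nuclear genes of the respiratory chain had a median of −0.22 with 1 of 38 called with the block (adjusted p = 0.00263, adjusted p = 0.923 with an estimated correlation). Heat shock chaperones (median −0.20), haploid-specific genes (−0.15), autophagy genes (−0.13) and cell wall genes (−0.11) passed with adjusted p of 0.0156 to 0.0452, and with an estimated correlation adjusted p = 0.540 for the cell wall and 0.923 for the other three. Ribosomal protein genes (median 0.25, 138 genes) and ribosome biogenesis genes (median 0.23, 82 genes) were higher with no member called, with and without the block (adjusted p = 4.00e-07 and 1.10e-06, for both adjusted p = 0.923 with an estimated correlation). The sucrose libraries numbered 2 stood apart in these gene groups. Ribosomal protein genes held 5.86% of counts in the 2SA library and 4.10% in the WT library numbered 2, against 9.69% to 13.4% in the other sucrose libraries, and stress genes 2.17% and 3.40% against 0.617% to 1.33%. Without all libraries numbered 2, the medians in sucrose were 0.20 for ribosomal proteins, 0.18 for ribosome biogenesis, −0.37 for stress and −0.16 for glycolysis (camera adjusted p = 5.63e-07, 4.05e-04, 3.94e-05 and 0.00256), while heat shock chaperones turned to 0.14 (adjusted p = 0.812).

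SNZ3 lost its call in sucrose without any of 8 single libraries (adjusted p 0.0547 to 0.232, highest without 2SA sucrose library 1), and ADH7 without 2SA sucrose library 1 or 2 (adjusted p = 0.102 and 0.0567). The lower calls numbered 0 without either of these libraries and 1 without WT glucose library 2 or 3, 2SA glucose library 1 or 2, or WT sucrose library 2 or 3, and the higher calls numbered 2 without 2SA sucrose library 3. With all libraries numbered 2 left out, the block within carbon source called 2 higher and 13 lower in sucrose and 2 higher and 8 lower in glucose.

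**Figure D2:**
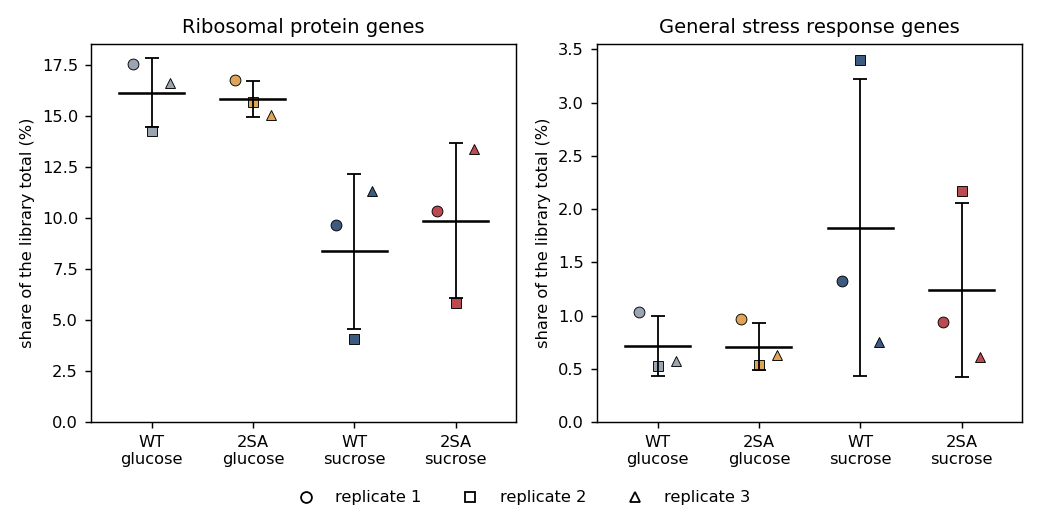
Share of each library's counts (%) held by the ribosomal protein genes and by the general stress response list, by group, with 1 symbol per replicate number and the mean ± SD of 3 replicates. The sucrose libraries numbered 2 have the lowest ribosomal protein shares (5.86% and 4.10%) and the highest stress shares (2.17% and 3.40%) of all 12 libraries.

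**Figure D3:**
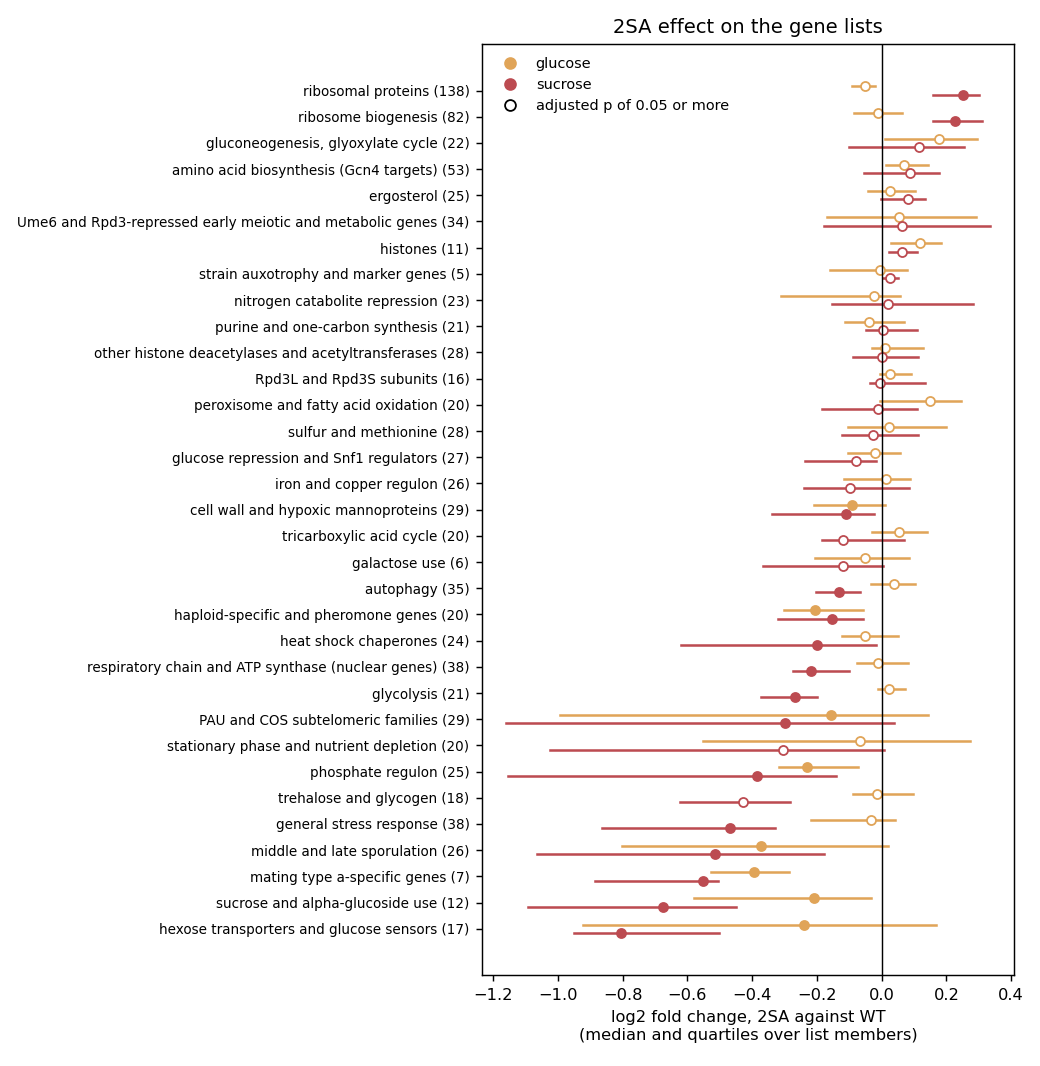
Median log2 fold change of 2SA against WT (points) with quartiles over list members (lines) for 33 gene lists in glucose and in sucrose, with the number of genes tested in parentheses and open points where the camera adjusted p was 0.05 or more. Hexose transporters lie lowest in sucrose at −0.80, and ribosomal proteins highest at 0.25.

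Growth in sucrose in place of glucose changed far more genes. In WT, SUC2 rose from 36.8 ± 19.4 to 677 ± 388 CPM (log2 4.20 ± 0.67, adjusted p = 0.0114, n = 3 per group), and the monocarboxylate transporter gene JEN1 from 17.0 ± 6.78 to 452 ± 257 CPM (log2 4.73 ± 0.71, adjusted p = 0.0102). The low-affinity glucose transporter gene HXT1 fell from 201 ± 83.9 to 17.4 ± 15.0 CPM (adjusted p = 0.0413), and FMP48, which encodes a kinase found in mitochondria, from 117 ± 28.7 to 24.9 ± 5.26 CPM (log2 −2.23 ± 0.23, adjusted p = 0.00232). 177 genes were called higher and 32 lower, with 1461 genes at an unadjusted p under 0.05. Scaling by total count gave 306 and 30, and DESeq2 343 and 199. The largest increases besides these were in RGI2, which has a role in respiratory growth (2.69 ± 3.04 to 173 ± 192 CPM), the peroxisomal thiolase gene POT1 (4.76 ± 0.84), SPG4 (4.70 ± 1.10), which is needed for survival in stationary phase, and the acetate transporter gene ADY2 (4.51 ± 0.83). Among the largest decreases were the acid phosphatase gene PHO3 (log2 −1.78 ± 0.29), the ribosomal protein gene RPL9A (−1.70 ± 0.41), GAS3 (−1.18 ± 0.23) and RPS29A (−1.13 ± 0.23). Each of these genes lay apart in the replicates of both carbon sources, and HXT1, PHO3, RPL9A and RPS29A have near copies.

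For gluconeogenesis, the glyoxylate cycle and use of small carbon sources the median was 1.53 over 22 genes, with 10 called and 17 higher adjusted over the list alone (camera adjusted p = 5.23e-10). Its called members included the alcohol dehydrogenase gene ADH2 (log2 3.93 ± 0.69) and the carnitine carrier gene CRC1, which rose from 7.17 ± 1.31 to 70.7 ± 15.4 CPM (log2 3.30 ± 0.35, adjusted p = 0.00239). Respiratory chain and ATP synthase genes had a median of 0.99 over 38 genes, with 7 called and 30 higher adjusted over the list alone (adjusted p = 2.72e-13). NDE2 (log2 2.84 ± 0.55), STF1 (1.44 ± 0.21) and ATP17 (1.12 ± 0.21) were among the called members. Tricarboxylic acid cycle genes (median 0.81) had 4 of 20 called and 8 higher adjusted over the list alone, with CIT3 at 1.80 ± 0.39 and LSC2 at 1.20 ± 0.18. Peroxisome and fatty acid oxidation genes (median 0.82) had 4 of 20 called and 9 higher adjusted over the list alone, with POX1 at 3.22 ± 0.65 and CAT2 at 2.66 ± 0.54. General stress genes (median 1.13) had 4 of 38 called and 6 higher adjusted over the list alone, led by SIP18 (2.39 ± 0.48), PAI3 (2.19 ± 0.39) and PRX1 (2.09 ± 0.30). Autophagy genes (median 0.36, 2 called and 5 higher adjusted over the list alone), the stationary phase list (0.62, 3 higher and 1 lower), nitrogen catabolite genes (0.38, with GDH2 called at 1.90 ± 0.30) and the list of Ume6- and Rpd3-repressed genes (0.28, 2 higher and 1 lower) also passed. Of the last list ACS1 (2.03 ± 0.38) and CAR2 (1.79 ± 0.24) are metabolic genes, while the meiotic gene SPO16 fell by 1.69 ± 0.28. For each of these lists adjusted p = 0.693 with an estimated correlation.

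Lists that ranked lower in sucrose were the ribosomal proteins (median −1.03, 3 of 138 called and none adjusted over the list alone, adjusted p = 4.14e-29), ribosome biogenesis (−0.41, 82 genes), ergosterol synthesis (−0.44, 25 genes), histones (−0.31, 11 genes), a-specific genes (−0.36, 7 genes) and haploid-specific genes (−0.35, with SST2 called at −0.93 ± 0.21). For these lists too, adjusted p = 0.693 with an estimated correlation. In the list of sucrose and alpha-glucoside use SUC2 and the maltase gene MAL32 (log2 2.33 ± 0.52, near-identical to MAL12) were called, but the list had an adjusted p of 0.0737. Of the hexose transporters HXT1 alone was called, and that list had an adjusted p of 0.540. Without the libraries numbered 2, which had the lowest ribosomal protein and highest stress shares of the sucrose libraries, the median was −0.75 for ribosomal proteins (adjusted p = 1.17e-35), while stress genes (0.16, adjusted p = 0.316) and ribosome biogenesis (0.09, adjusted p = 0.660) did not pass. Gluconeogenesis (1.38, adjusted p = 5.26e-09) and the respiratory chain (0.54, adjusted p = 1.19e-09) did.

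The counts of called genes moved with single libraries. Without WT glucose library 1, 2 or 3, 64, 10 and 20 genes were called higher and 4, 2 and 1 lower. Without WT sucrose library 1, 2 or 3 they were 57, 100 and 256 higher and 2, 9 and 170 lower. Without 2SA glucose library 1, 2 or 3 they were 145, 116 and 141 higher and 14, 10 and 12 lower. Without 2SA sucrose library 1, 133 were higher and 15 lower. CRC1 and FMP48 kept their calls without any single library, whereas SUC2 and JEN1 lost theirs without WT glucose library 2 or 3 (adjusted p = 0.0755 and 0.0715 for SUC2, 0.0613 and 0.0614 for JEN1). HXT1 lost its call without any of 8 single libraries (adjusted p 0.0535 to 0.128).

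In the 2SA mutant, the sucrose response covered 98 genes called higher and 17 lower, with 1101 genes at an unadjusted p under 0.05. Scaling by total count gave 185 and 14, and DESeq2 218 and 129. SUC2 rose from 44.2 ± 30.1 to 401 ± 182 CPM (log2 3.18 ± 0.64, adjusted p = 0.0338, n = 3 per group), JEN1 from 12.9 ± 5.39 to 368 ± 286 CPM (4.84 ± 0.72, adjusted p = 0.0169) and CRC1 from 8.26 ± 2.53 to 81.0 ± 33.1 CPM (3.29 ± 0.35, adjusted p = 0.00276). The glucose transporter gene HXT3 fell from 984 ± 479 to 155 ± 45.3 CPM (log2 −2.67 ± 0.50, adjusted p = 0.0319) and the pyruvate kinase gene CDC19 from 823 ± 193 to 250 ± 110 CPM (−1.72 ± 0.37, adjusted p = 0.0411). FMP48 (log2 −2.34 ± 0.23), PHO3 (−1.48 ± 0.28), TEC1 of filamentous growth (−1.30 ± 0.25) and YNR014W (−1.26 ± 0.28) fell too, and SPG4 (5.12 ± 1.13), POT1 (4.76 ± 0.84), ADY2 (4.67 ± 0.84) and ADH2 (3.78 ± 0.69) rose. The Ty feature YER138C rose by 3.52 ± 0.70 and has near-identical copies. HXT1 (log2 −2.93 ± 0.80, adjusted p = 0.0927) and INO1 of inositol synthesis (1.97 ± 0.45, adjusted p = 0.0501) missed the threshold. HXT3 has near copies and CDC19 overlaps another feature.

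Gluconeogenesis genes had a median of 1.47 in 2SA, with 9 of 22 called and 17 higher and 1 lower adjusted over the list alone (camera adjusted p = 8.53e-12). Respiratory chain genes (median 0.76, 3 of 38 called, 13 adjusted over the list alone), the tricarboxylic acid cycle (0.66, 3 of 20 called, 7 adjusted over the list alone), peroxisome genes (0.60, 3 of 20 called, 9 adjusted over the list alone), nitrogen catabolite genes (0.34, with GDH2 at 2.10 ± 0.30) and the Ume6- and Rpd3-repressed list (0.24, 2 higher and 1 lower) rose. Glycolysis had a median of −0.75 with CDC19 called and 7 of 21 lower adjusted over the list alone (adjusted p = 1.79e-04). Ribosomal proteins (median −0.75, none of 138 called), the phosphate regulon (−0.52, with PHO3 called and 3 lower adjusted over the list alone), ergosterol genes (−0.38), histones (−0.34), haploid-specific genes (−0.39, with SST2 called at −1.03 ± 0.21) and a-specific genes (−0.87, none called and 4 of 7 lower adjusted over the list alone) fell as lists. For each of these lists adjusted p = 0.580 with an estimated correlation. Stress genes had a median of 0.57 with PAI3 (1.95 ± 0.39) and PRX1 (1.75 ± 0.30) called and 5 higher adjusted over the list alone, and ribosome biogenesis a median of −0.21 (adjusted p = 0.0142 and 0.0169, adjusted p = 0.910 and 0.943 with an estimated correlation). Without the libraries numbered 2 the stress median was −0.25 (adjusted p = 0.641) and ribosome biogenesis turned to 0.17 and passed as higher (adjusted p = 0.0254), while ribosomal proteins stayed lower at −0.45 (adjusted p = 1.44e-17). Scaled by total count, the stress list did not pass (adjusted p = 0.123).

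SUC2 lost its call in 2SA without any of 8 single libraries (adjusted p 0.0537 to 0.184), and JEN1 without 2SA glucose library 1, 2 or 3 or 2SA sucrose library 1 (adjusted p 0.0524 to 0.127). HXT3 lost its call without any of 6 and CDC19 without any of 9 single libraries (adjusted p 0.0537 to 0.129 and 0.0523 to 0.154). CRC1 and FMP48 kept theirs. The calls numbered 9, 2 and 3 higher and 1, 1 and 2 lower without 2SA glucose library 1, 2 or 3, and 4 and 10 higher and 1 and 1 lower without 2SA sucrose library 1 or 2. Without 2SA sucrose library 3, 83 were higher and 11 lower, without WT glucose library 1, 73 and 9, without WT glucose library 2 or 3, 37 and 3, and without WT sucrose library 2, 121 and 36.

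**Figure D4:**
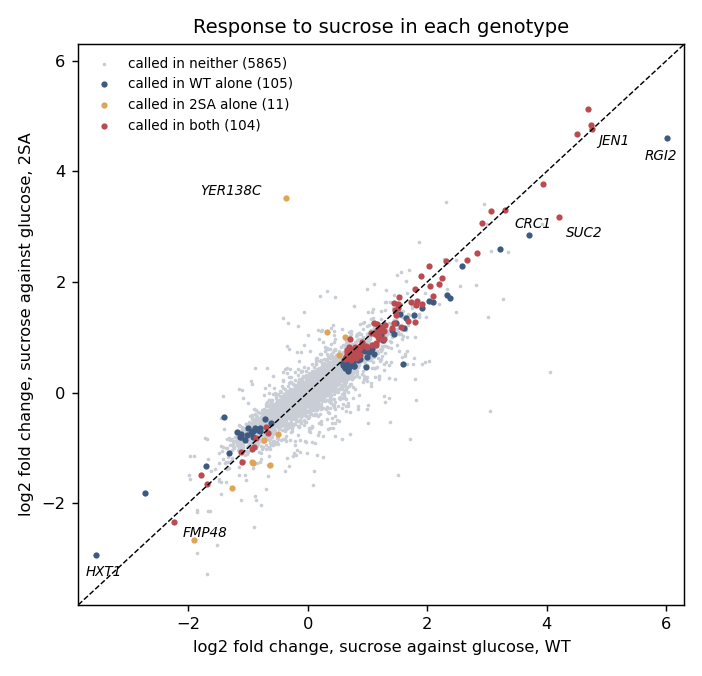
Log2 fold change of sucrose against glucose in WT (horizontal) and in 2SA (vertical) for 6085 genes, coloured by the genotype in which the gene was called, with a dashed line where both are equal. Of 209 genes called in WT and 115 in 2SA, 104 were called in both, but no gene was called for the difference of the responses.

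The test of the difference between genotypes in the sucrose response, the interaction, called 0 genes with edgeR. 10 genes had an unadjusted p under 0.05 where chance gives 304, in a fit that counts deviations shared by number as spread. In the simulation with independent libraries this test recovered 7 of 100 genes changed by a fold of 2. It was not simulated with deviations shared by number, so its power in these libraries is not known. 0 calls therefore do not show equal responses. The interaction also called 0 with DESeq2, with limma-voom and with either block. With the planned block 26 genes, and with the block within carbon source 302 genes, had an unadjusted p under 0.05. For SUC2 the interaction was −1.02 ± 0.83 (adjusted p = 1.0) and for HXT1 0.61 ± 1.06 (adjusted p = 1.0). The overlap of calls was 94 higher genes (177 in WT, 98 in 2SA, 2.85 for independent lists) and 10 lower genes (0.0894 for independent lists). The responses correlated across genes with r = 0.883, with 86.9% of genes of the same sign. WT and 2SA libraries of the same number deviate together within each carbon source, so both responses carry the same deviations. This can raise the correlation, the share of the same sign and the overlap above the value for independent lists. Genes are not independent replicates, so no p-value goes with these correlations. Of 762 genes called for the mean sucrose response of both genotypes, 545 (71.5%) had the smaller response in 2SA. The slope through the origin of the 2SA on the WT response was 0.894, and that of the WT on the 2SA response 1.04. Without 2SA sucrose library 3 the first slope was 1.05.

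7 lists passed for the interaction, with no member called. Ribosomal proteins (median 0.28, camera adjusted p = 8.48e-16) and ribosome biogenesis (0.22, adjusted p = 1.27e-08) had a positive difference. General stress (−0.35, adjusted p = 1.95e-04) and the respiratory chain (−0.20, adjusted p = 1.36e-04) had a negative one. Glycolysis (−0.27), the phosphate regulon (−0.18) and autophagy (−0.16) were negative as well. For all 7 lists adjusted p = 0.987 with an estimated correlation. With the block within carbon source 10 lists passed, where the lowest was adjusted p = 0.397 with an estimated correlation. Sucrose and alpha-glucoside use (−0.12, adjusted p = 0.0170) and peroxisome genes (−0.15, adjusted p = 0.00667) were among those that joined, with adjusted p = 0.613 and 0.397 with an estimated correlation. Without the block 10 of the 33 lists passed in no contrast (lowest adjusted p = 0.118), among them galactose use, iron and copper, and the Rpd3L and Rpd3S subunits. 3 of the 10 passed with the block within carbon source. Trehalose and glycogen genes did so in sucrose (median −0.38, adjusted p = 1.19e-06, adjusted p = 0.477 with an estimated correlation) and for the interaction (−0.24, adjusted p = 8.90e-07, adjusted p = 0.397 with an estimated correlation). Glucose repression regulators (−0.07, adjusted p = 0.0470) and amino acid biosynthesis genes (0.08, adjusted p = 0.0390) did so in sucrose, with adjusted p = 0.486 and 0.625 with an estimated correlation.

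The 2SA effects in glucose and in sucrose, which share no library, correlated across genes with Pearson r = 0.690 and Spearman rho = 0.499, and 67.2% of genes had the same sign. Pearson r was 0.348 without WT glucose library 1. 1 gene was called higher and 2 lower in both carbon sources. With the block within carbon source 4 were higher (0.0161 for independent lists) and 22 lower (0.354) in both, so that all 22 genes called lower in glucose were also called lower in sucrose. The 2SA effect in glucose and the sucrose response of WT share the WT glucose libraries. Their covariance across genes was 0.00278 (r = 0.0169), against 0.0577 ± 0.00277 in 100 simulations of unchanged groups with independent replicates (r = 0.502) and 0.0101 from the replicate deviations of these libraries. The differences from these were −0.0549 and −0.00728. The simulation left out that WT and 2SA libraries of the same number deviate together, so no conclusion is drawn from the first difference. Without 2SA glucose library 1 the covariance was −0.0135, and without WT glucose library 1 it was 0.0470. The 3 shared libraries were not split, since 1 part would hold a single library, and part of any relation may come from the shared libraries.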

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

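The tests of a few chromosome ends, of genes without a near copy by odds ratio and of library size were chosen only after the result was seen, as were all values with a block within carbon source and those without the libraries numbered 2.

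7 gene lists had a sucrose response that differed between 2SA and WT by the interaction test of camera, with no member called. The median log2 difference, 2SA minus WT, was 0.28479 for ribosomal proteins, 0.21559 for ribosome biogenesis, −0.35034 for general stress, −0.26825 for glycolysis, −0.20284 for the respiratory chain, −0.17874 for the phosphate regulon and −0.15818 for autophagy. For all of them adjusted p = 0.987 with an estimated correlation. Passing lists were counted in 100 splits drawn from the 12 libraries and fitted without a block. 90 of them had at least as many as the real one (7, highest other 24). The real labels place 1 library of each same-numbered pair in each genotype, while other splits can place both in 1 group. Such splits carry the shared deviations into the contrast, so the 90 of 100 does not measure chance. Chance is not excluded for the lists. The real split called 0 genes, which all 100 splits reach (highest other 462), so the count of calls decides nothing. A split that calls 462 genes points to a structure of the samples, and the libraries of a number share deviations within each carbon source.

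The smaller response of ribosomal protein genes in 2SA was set against 2 technical explanations. Without all libraries numbered 2 their median difference was 0.31714, and with scaling by total count 0.27016, which argues against these libraries and the TMM factors as the whole cause. These tests do not cover the stress genes, whose list did not pass without the libraries numbered 2 in WT (median 0.16, adjusted p = 0.316) or in 2SA (−0.25, adjusted p = 0.641). Those values are the sucrose responses of each genotype and not their difference. For 2SA against WT in sucrose the stress list stayed lower and passed with camera without these libraries. A smaller response of the mutant is a hypothesis that stays open, beside unequal harvest points of the sucrose cultures, a question that the correlation of 0.2396 given for the libraries numbered 2 did not settle.

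The sucrose libraries numbered 2 stood apart from the other sucrose libraries in both genotypes, and their deviations from the group means correlated with r = 0.847 across genes. Totals of 2 of these 2 libraries lay inside the range of the other 10, which argues against library size. Against genes of matched length the ribosomal proteins kept a deviation of −1.327 log2, of −1.36 unmatched, which argues against a length bias. Cultures further along the change from glucose to sucrose may be a cause, but the correlation with the sucrose response of the other libraries was 0.2396 on average, 0.0744 and 0.405 in the separate directions, and leaves this open. No group of the design separates these libraries from the others.

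For called genes between 2 groups there are 10 splits of 6 libraries, too few for a share under 0.05. The real split called 5 genes in glucose (highest other 0), 4 in sucrose (highest other 1), 209 for the sucrose response of WT (highest other 0) and 115 for that of 2SA (highest other 0), in each case 1 of 10 splits with as many. For passing lists 7, 5, 4 and 5 of the 10 splits had as many as the real 8, 15, 15 and 15, with 23, 22, 19 and 19 as the highest of the others. With the block within carbon source, genotype labels can be swapped in 4 ways per carbon source, again too few, with 29 real calls in glucose and 112 in sucrose (highest other 0 in both, 1 of 4 each). For the mean 2SA effect over both carbon sources 1 of 32 swaps, the real one, called as many as 152 genes (highest other 0), a share under 0.05. This speaks against chance labels within the pairs alone, in a fit chosen after the data were seen. It does not tell the mutation from another difference between the strains.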

How the results depend on the processing

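The block within carbon source and the settings that leave out all libraries of 1 number were chosen after the data were seen. The interaction called 0 genes under each setting run. Without all libraries numbered 2 the median of 4 passing lists turned, for ribosome biogenesis from −0.41 to 0.09 in WT (adjusted p = 0.660) and from −0.21 to 0.17 in 2SA (adjusted p = 0.0254), for stress in 2SA from 0.57 to −0.25 (adjusted p = 0.641) and for heat shock chaperones in sucrose from −0.20 to 0.14 (adjusted p = 0.812), and the cause was not tested. With the replicate block 2 genes were higher and 7 lower in 2SA in glucose, 1 and 9 in sucrose, 363 and 273 in sucrose against glucose in WT and 214 and 133 in 2SA. Across carbon sources the libraries share only a number (r of the deviations 0.359, −0.0948 and 0.479 in WT, 0.250, −0.195 and 0.335 in 2SA, highest with the own number in 4 of 6). With the block within carbon source the calls were 7 and 22 in glucose and 14 and 98 in sucrose, and with the libraries numbered 2 left out as well 2 and 8, and 2 and 13. For the mean 2SA effect the calls were 6 and 32 without a block, 7 and 54 with the replicate block, 17 and 135 with the block within carbon source, and 11 and 53 with the latter without the libraries numbered 2. DESeq2 called 5 and 26, 10 and 36, 343 and 199, and 218 and 129 genes higher and lower in the order given, and its cause was not tested. With all libraries numbered 1, 2 or 3 left out, fewer libraries were fitted and glucose gave 0 and 0, 1 and 0, and 0 and 0, sucrose 0 and 1, 0 and 0, and 0 and 0, WT 2 and 0, 0 and 0, and 4 and 0, and 2SA 4 and 1, 0 and 0, and 4 and 0. Fits of the compared groups alone, with fewer samples, gave 1 and 0, 0 and 0, 9 and 1, and 4 and 1. A fold over 2 left 78 and 16 genes in WT and 50 and 11 in 2SA, and glmTreat 14 and 1, 5 and 1, and 0 lower in sucrose. At a mean of 10 CPM 1 was higher and 1 lower in glucose and 1 lower in sucrose, and voom called 1 lower in sucrose. Scaling by total count called 306 genes higher in WT and 185 in 2SA, where it moved the median of all genes from 0.04 to 0.18 and from 0.02 to 0.15. The cause of the other differences was not tested.

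With the replicate block autophagy in sucrose no longer passed (adjusted p = 0.0590) and glycolysis in WT did (adjusted p = 0.0436). With an estimated correlation 0 lists passed in each of the 5 contrasts, and with fry 0, 0, 1, 1 and 0. With the block within carbon source fry passed 3 lists in glucose, 4 in sucrose and 0 for the interaction. Leaving out 1 library, the calls ranged from 1 to 2 higher and 0 to 4 lower in glucose, 1 to 2 and 0 to 3 in sucrose, 10 to 256 and 1 to 170 in WT, and 2 to 121 and 1 to 36 in 2SA. The extremes were without WT glucose library 2 (10) and 3 (1) and WT sucrose library 3 (256 and 170) in WT, and without 2SA glucose library 2 (2) and 1 (1) and WT sucrose library 2 (121 and 36) in 2SA. Passing lists ranged from 8 to 14, 11 to 20, 7 to 19, 12 to 18 and 5 to 12, with 14 without 2SA glucose library 1, 7 without WT sucrose library 2, and for the interaction 12 without WT glucose library 1 or 2SA sucrose library 2 and 11 without 2SA glucose library 3 or WT sucrose library 2. The correlation of the 2SA effects ranged from 0.348 (without WT glucose library 1) to 0.727, the slope of the sucrose responses from 0.720 to 1.05, and the covariance of the glucose effect with the WT response from −0.0135 to 0.0470, so that it turned its sign and the slope passed 1. Depth limits genes such as DDI3, at 0.271 CPM in 2SA.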

Other observations

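The genes called for the mean 2SA effect and their distances to chromosome ends were chosen after the values were seen, as was the block within carbon source, and so were the tests of few chromosome ends and of the odds ratio.

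Averaged over glucose and sucrose with the block within carbon source, 17 genes were higher and 135 lower in 2SA, against 6 and 32 without a block and 11 and 53 with the block but without the libraries numbered 2. The values of single genes here come from the blocked fit. SNO1 (log2 1.01 ± 0.10) and SNZ1 (0.94 ± 0.09), a neighbouring pair for vitamin B6 synthesis, were higher, while their relatives near chromosome ends, SNZ2 (−1.11 ± 0.16) and SNO2 (−1.15 ± 0.13), were lower. SNZ2 has the near copy SNZ3, itself lower (−3.50 ± 0.21), and SNO2 has the near copy SNO3. The values of SNZ2 and SNO2 are therefore uncertain, and a fall of their own is not shown. BNA2 (−1.94 ± 0.44), BNA1 (−1.40 ± 0.34) and BNA5 (−1.10 ± 0.18) of NAD synthesis were lower, whereas BNA4 (−0.56) and BNA6 (−0.58) were not called (adjusted p = 0.158 and 0.102), and BNA2 and BNA5 overlap other annotated features. THI4 of thiamine synthesis was lower by 0.99 ± 0.23 on the log2 scale. Of 26 middle and late sporulation genes 2 were lower, DIT1 (−1.65 ± 0.33) and SPR3 (−1.55 ± 0.28). Of 34 genes in the Ume6- and Rpd3-repressed list 3 were lower, REC8 (−0.89 ± 0.17), MSH4 (−0.63 ± 0.13) and HOP2 (−0.60 ± 0.14), and REC102 was higher (0.65 ± 0.11). Outside these lists MPC54 (−1.78 ± 0.16), DTR1 (−1.49 ± 0.23) and HFM1 (−0.96 ± 0.08) were lower. The mating genes FUS1 (−1.46 ± 0.23), AFB1 (−1.38 ± 0.17) and AGA1 (−0.77 ± 0.17) were lower as well. The counts of lower genes in the fixed lists were 2 of 20 for haploid-specific and pheromone genes, FUS1 and AGA1, and 1 of 7 for a-specific genes. Of 38 gag-pol open reading frames of Ty elements, which have near-identical copies, 4 were called higher and 1 lower. 11 of the 38 had a positive value and the median of all 38 was −0.27, with a total of 1675 ± 429 CPM in WT and 1623 ± 112 in 2SA in glucose, and 1411 ± 163 and 1304 ± 125 in sucrose (n = 3 each).

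Genes near chromosome ends were lower in 2SA. Within 10 kb of an end the median log2 effect without a block was −0.63 over 87 genes, and it was −0.22 at 10 to 20 kb (119 genes), −0.07 at 20 to 30 kb (141 genes) and 0.01 beyond 100 kb (4601 genes). Of the genes called lower with the block within carbon source, 70 of 135 for the mean effect, 20 of 22 in glucose and 49 of 98 in sucrose lay within 30 kb of an end, where 347 of 6082 genes lie (Fisher's exact test, adjusted p = 5.75e-52, 3.28e-23 and 2.63e-35). Without a block it was 27 of 32 for the mean effect (adjusted p = 9.17e-29). The lists of alpha-glucoside use (11 of 12 genes) and of PAU and COS families (23 of 29) lie mostly in this window, and those of hexose transporters (6 of 17) and the phosphate regulon (5 of 25) in part. The median of −0.19 in the window was below the lowest of 10000 random lists matched on expression (−0.06). The Fisher tests and the random lists take genes as units, but genes are not independent replicates. Of the 70 genes called lower in the window for the mean effect with the block, 41 have a near copy. These tests therefore do not measure the spread between cultures or strains.

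The tables argue against a few altered ends and, in part, against reads shared with near copies. 30 of 32 ends had a median below that of distant genes (exact sign test, p = 2.46e-07). Some lay only just below it, such as the left end of chromosome III (0.0075, against 0.0093). Called lower genes lay at 22 of the 32 ends, with 8 at the left end of chromosome XV. The sign test takes ends as independent units, and both counts include genes with near copies. If copies share reads, a change at 1 end can lower counts at other ends too. Genes without a near copy called lower in the window include SEO1 (chromosome I), PHO89 (II), ADH7 (III), IRC4 (IV), AGP3 (VI) and YOL160W (XV). Their places on several chromosomes argue against a loss or rearrangement of a few ends as the whole source of the pattern. Among genes without a near copy, 29 of 229 in the window and 42 of 4360 far away were called lower. The odds ratio was 14.88, with a 95% interval from 8.75 upwards. This argues against reads shared with near copies, as defined here, as the cause for those 29. Matches below the identity or length limit were not counted, and the 29 include the family members COS10 and COS12. Sharing through such weaker matches stays open for the 29 as well. The median of genes without a near copy differed by only −0.1061 (SE 0.0259) and leaves sharing open for the rest. A difference in growth state stays open. 102.8% of the median effect in glucose stayed after the axis of the libraries numbered 2 was taken out, but that axis hardly followed the effect (r = 0.0540), so the test does not decide. A difference in strain background was not tested.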
